A study of Arabidopsis thaliana with 6 samples.

How the data were processed

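Rosette leaves were harvested from plants grown for 2 weeks on plates and 10 days on soil, per the labels' protocols, and total RNA was amplified to Cy3-labelled cRNA for Agilent Arabidopsis oligonucleotide arrays. Per the file headers, each array was scanned and extracted with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes list version 9.1. The deposited intensity values of a spot comprise its mean pixel value, its local background and a processed signal. Per the file headers, the processed intensity is background-subtracted and detrended within the array, with surrogate values in place of very low signals, and it is not normalized between arrays. The deposited series table holds intensity values that equal the processed signal at all 45220 spots of every array (within 0.01%), on a linear scale, uncentred, with column medians from 192 to 305. Surrogates stood for 13.6% to 18.6% of non-control spots, so folds of dim genes are uncertain, and the size of this effect was not tested. No spot was saturated, and 4 to 25 spots per array carried an outlier flag.

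Control spots were left out and outlier spots set to missing. The log2 processed signal was averaged over spots of 1 probe and the array's 75th percentile subtracted. A probe was kept if it was well above background on all 3 arrays of at least 1 genotype. Of 43603 probes, 36491 were paired with a locus of the gene table (TAIR10.1 assembly), 34348 through an accession, 1414 through a locus code, 714 by symbol and 15 by synonym, for 26177 loci. Of the paired probes, 493 also listed an accession of another locus. The remaining 7112 probes were kept out of the main comparison. Probe coordinates are those of the files, on TAIR10 per the file headers. A gene with several probes is represented by the probe with the highest mean. A gene is called not well above background in a genotype only if none of its probes was on any array of it. Its fold is then a lower bound, computed from the bright group's mean against the mean of, per array, the higher of the dim probe's own value and the lowest signal of any probe well above background.

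Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated statistics, two-sided, genotype as the only term) with Benjamini-Hochberg adjustment over 19357 genes, at an adjusted p under 0.05, also with a log2 change of at least 1. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. For 33 gene lists with 528 entries, 475 of them measured, camera with a preset correlation of 0.01 tested whether list members ranked apart from all other genes, adjusted over the lists. It called 14 lists, and with the correlation estimated from the data it called none. The estimate reached 0.907 (aliphatic glucosinolate), but was 0.0134 for the karrikin list and -0.00198 for ABA response, near or below the preset. Those lists lost their calls too, so the size of the correlation alone does not account for the loss. List calls below are those at the preset value. Members were matched by locus code, and 19 of the listed symbols are not in the gene table. Symbol families (genes sharing the letters before the first digit, at least 8 measured) were tested likewise. The steps were tested on simulated data for this comparison (19357 genes, 3 arrays per group). Of genes changed by 1 on the log2 scale 73% were called, of genes changed by 2 93%, and 6.49% of calls were unchanged genes. The simulated noise was independent between genes, without slide effects or surrogate values, and far fewer genes were changed than in the data. These shares therefore need not hold for the data.

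The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where a choice is said to have been made afterwards. The rule names all measured genes of the strigolactone and karrikin lists and the 10 largest rises and 10 largest falls among called genes with a symbol and groups that do not overlap. From each list it takes up to 4 members with the smallest adjusted p, or up to 2 given as values where none passes. Some genes that pass this rule are left out of the text for length. Genes named for probes that disagree were chosen after their values were seen.

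Per the file headers, the arrays lie on 3 slides, and replicate 1 of both genotypes shares a slide, as do replicates 2 and 3. Slides 1 and 2 were scanned on 1 day and slide 3 on another. WT was at position 1 and d14 kai2 at position 4 of every slide, so position and genotype cannot be told apart. The deviations of same-numbered arrays from their group means correlated at 0.06, 0.29 and 0.23 across genes, and each array correlated best with the one of its own number. The slide is therefore regarded as a batch that holds both genotypes. The main fit has no slide term, and the slide enters as a block only in alternative fits. List shifts are also given within slides. Replicate arrays of a genotype correlated at 0.987 to 0.995 across genes, and arrays of different genotypes at 0.956 to 0.962.

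Alternatives covered background correction (normexp with an offset of 50), quantile and median scaling, the series table, filters on dim probes, the slide as a fixed or random block, other ways to combine probes, a trended robust variance, outlier spots kept, and each array or replicate number left out. Chosen after seeing the data were the fits without genes of the rich windows, with unpaired probes kept, and with D14 and KAI2 left out of their lists. List shifts within slides are given for called lists.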

Results

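Transcript levels were measured in rosette leaves of Arabidopsis thaliana plants 24 days old, in the wild type (WT, Col-0 by the sample titles) and in the d14 kai2 mutant. D14 is the receptor of strigolactones, carotenoid-derived hormones that restrain shoot branching. KAI2 is a related protein that perceives karrikins, butenolide compounds of smoke, and is thought to sense an unidentified compound made by the plant. The title of the series asks how these pathways act on other plant hormones, so the comparison of mutant and WT was read through gene lists for the synthesis, breakdown and response of each hormone. Each genotype had 3 biological replicates, each on 1 single-colour array. The 75th percentile of the processed signal was 2015 to 2465 intensity units on WT arrays and 1623 to 1983 on d14 kai2 arrays. Every mutant array was thus dimmer than every WT array before scaling. Of the 43803 non-control spots, 68.5% to 72.1% per array were well above background. Values below are log2 signals relative to the array's 75th percentile, given as mean ± SD over 3 arrays, and log2 changes are d14 kai2 minus WT. The number of arrays limits the precision.

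The mutated genes were examined first. The KAI2 probe (AT4G37470, chromosome 4, 17617089 to 17617148, TAIR10) read 3.26 ± 0.04 in WT and 1.31 ± 0.01 in d14 kai2, a 3.86-fold lower signal (adjusted p = 3.57e-05), and stayed well above background on all 6 arrays. D14 (AT3G03990, chromosome 3) was detected on all arrays of both genotypes by 3 probes. The brightest of them (1034657 to 1034716) read 2.71 ± 0.15 in WT and 2.34 ± 0.11 in the mutant, a log2 change of -0.37 with an SE of 0.11 (adjusted p = 0.0474). The other probes changed by -0.19 (1034001 to 1034059) and -0.25 (1034131 to 1034190), with adjusted p of 0.255 and 0.142 over all probes of the array, where the brightest probe had 0.0674. The D14 call was lost when any 1 array other than WT replicate 3 was left out (adjusted p from 0.0639 to 0.134). The labels give no alleles, so a probe may lie outside the lesion and a D14 transcript that is still detected says nothing about the protein.

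Of 19357 genes tested, 4744 changed at an adjusted p under 0.05. The level was higher in d14 kai2 for 2495 of them and lower for 2249, and 1356 changed at least 2-fold, 537 upward and 819 downward. The genotypes did not overlap at 8598 genes, 44.5% of those tested, where chance gives 10%. Scaling on the median in place of the 75th percentile gave 3092 higher and 1836 lower genes. Among the changed genes, 39 were not well above background on any WT array and 155 on any mutant array, and their folds are given as lower bounds. The mutant arrays were dimmer before scaling, and the effect of this on these counts was not tested. Fewer genes passed without WT replicate 2 (3100) or d14 kai2 replicate 2 (2822), and without both arrays of replicate 1 (1683) or 2 (1226). With the slide as a block the count was 6024, and as a random block 7665. The count of genes changed at least 2-fold was 853 with normexp background correction and 873 without both arrays of replicate 2.

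Of the largest rises among genes with a symbol, CYP96A5, a cytochrome P450, was at least 44.6-fold higher (adjusted p = 0.00019) and was not well above background in WT. FAR8 and FAR1 (AT5G22500), of the fatty acyl reductase family that makes fatty alcohols, were 44.2-fold and 39.4-fold higher, and the acyl-lipid desaturase gene ADS1 (AT1G06080) was 41.6-fold higher. MRD1 rose 25.2-fold, the MADS-box gene SHP1 16.5-fold, the auxin response repressor gene IAA34 17.3-fold and CYP707A2, which encodes an abscisic acid 8'-hydroxylase, 14.9-fold. RTFL15, a gene of the ROTUNDIFOLIA-like small peptides, rose at least 7.13-fold. Among the largest falls, PCR1 was at least 211-fold lower, DDB1B at least 114-fold, CRK14 at least 32.8-fold, CRK6 at least 28.6-fold, SEC14 at least 21.8-fold and the pathogenesis-related gene PR1 at least 15.4-fold. ECS1 fell from 4.47 ± 0.21 to -4.94 ± 0.65 (adjusted p = 3.98e-05). TAT3, a tyrosine aminotransferase gene induced by jasmonate, fell by 9.19 on the log2 scale, the terpene synthase gene TPS04 fell 78.6-fold and MSRB8 fell 74.9-fold, and each of these was well above background on 1 of the 3 mutant arrays, so these folds are uncertain. With single arrays left out, the log2 change of MSRB8 ranged from -7.39 to -5.40. ECS1, DDB1B, CRK6, CRK14 and MSRB8 lie in the chromosome stretches described at the end.

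All 6 measured genes of the karrikin list fell. DLK2, a D14 homologue whose transcript is a marker of KAI2 signalling, went from 1.26 ± 0.12 in WT to not well above background on any mutant array, at least 241-fold lower (adjusted p = 3.12e-05). KUF1 fell 7.49-fold, BBX20 4.82-fold, and the repressor genes SMXL2 and SMAX1, whose proteins are degraded after karrikin perception, 2.38-fold and 2.06-fold. The 2 probes of SMXL2 changed by -2.69 and -1.25. KUF1 lies in the chromosome stretches described at the end, and SMXL2 and BBX20 lie on chromosome 4, as KAI2 does. The list lay below the rest of the genes (median log2 change -2.11, camera adjusted p = 1.81e-07). With an estimated correlation its adjusted p = 0.164. The median change was -2.07, -2.09 and -2.18 within the 3 slides. Without KAI2 itself the list kept an adjusted p of 4.17e-06.

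The strigolactone list moved in both directions: of 13 measured genes, 4 rose and 6 fell, with the same counts when adjusted over the list alone (median -0.36, mean -0.08, adjusted p = 0.183). The median was -0.16 without d14 kai2 replicate 2 and -0.22 without WT replicate 3. The rises were in biosynthesis. MAX3, a carotenoid cleavage dioxygenase gene, was at least 3.02-fold higher and not well above background in WT. MAX4, the following dioxygenase of the pathway, rose by 5.32 on the log2 scale with an SD of 1.98 in WT, where 2 of 3 arrays were well above background (adjusted p = 0.011). D27 rose by 0.85 (adjusted p = 0.0168) and LBO1 by 0.76 (adjusted p = 0.0446). The D27 call was lost without d14 kai2 replicate 2 (adjusted p = 0.0549) or 3 (0.0545). The LBO1 call was lost without any 1 array other than WT replicate 3 (adjusted p from 0.0727 to 0.126). MAX1, which acts after MAX4, fell 3.86-fold. The repressor genes SMXL6, SMXL7 and SMXL8, whose proteins are removed when D14 signals, fell 1.89-fold, 1.44-fold and 8.95-fold, and the branching repressor gene BRC1 fell 14.9-fold (adjusted p = 0.000578). BRC2, CLAMT and MAX2 did not pass the test (log2 changes -0.36, -0.30 and 0.12). With single arrays left out, BRC2 ranged from -0.60 to -0.026, CLAMT from -0.48 to -0.16 and MAX2 from 0.065 to 0.18. The list was called when limited to probes above background on all 6 arrays (adjusted p = 0.0098) and with every probe on its own (0.0318). The former filter leaves out MAX3 and MAX4, which rose, so that call does not describe the whole list.

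**Figure D1:**
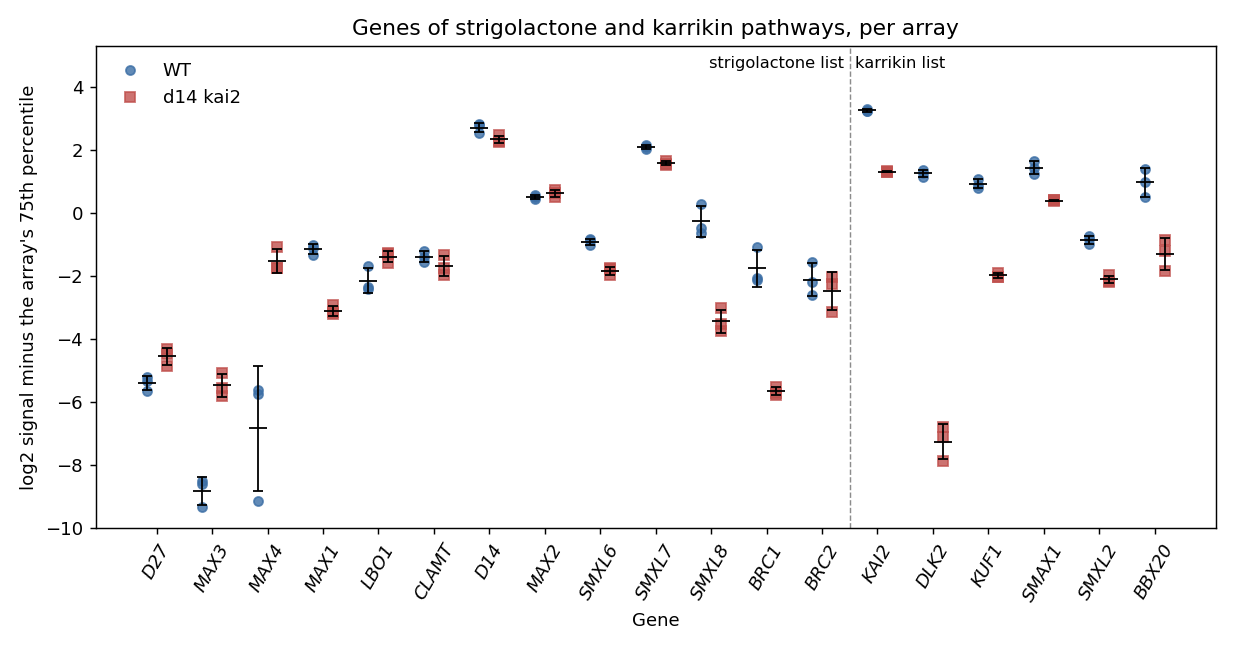
Log2 signal minus the array's 75th percentile (vertical axis) for each measured gene of the strigolactone and karrikin lists, with 3 WT arrays as circles and 3 d14 kai2 arrays as squares; bars give mean and SD. DLK2 fell from 1.26 in WT to a signal not well above background on any mutant array (at least 241-fold), while MAX3 and MAX4 were higher in the mutant.

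Genes of salicylic acid (SA), a hormone of defence against biotrophic pathogens, fell together. Of 16 measured SA response genes, 13 fell and none rose (15 fell when adjusted over the list alone). PR1 was at least 15.4-fold lower, the transcription factor gene WRKY70 fell 9.51-fold from 2.34 ± 0.49 to -0.90 ± 0.19 (adjusted p = 0.000702), WRKY54 fell by 4.42 on the log2 scale and was well above background on 1 mutant array, and the SA receptor gene NPR4 fell 2.07-fold. In the SA metabolism list, 11 of 15 genes fell and 2 rose (13 and 2 adjusted over the list alone). SARD1, a transcriptional activator of SA synthesis, fell 15.4-fold, EDS5, the exporter of its precursor from plastids, 6.05-fold, PBS3 13.1-fold at the brighter of probes that changed by -3.71 and -2.45, and DMR6, an SA hydroxylase gene, 3.12-fold. The median log2 change was -2.54 for SA response (camera adjusted p = 4.82e-09) and -1.64 for SA metabolism (7.84e-05). With an estimated correlation the adjusted p = 0.307 and 0.447. Within slides 1, 2 and 3 the SA response median was -2.11, -3.63 and -2.55, and the SA metabolism median -1.84, -1.91 and -1.92. NPR4 lies in the chromosome stretches described at the end. With probes above background on all 6 arrays the medians were -1.52 and -1.02, and with normexp background correction the SA response median was -1.63. On the same arrays the flower and floral transition markers were lower (median -1.32).

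Jasmonate (JA) lists also had negative medians, with few members past the test. Of 17 JA metabolism genes, 3 fell and none rose, and of 18 JA response genes, 4 fell and none rose, with the same counts adjusted over each list alone. LOX4, a lipoxygenase gene of JA synthesis, fell 7.04-fold and was well above background on 2 mutant arrays, the allene oxide cyclase gene AOC3 fell 7.38-fold with 1 mutant array above background, and the repressor gene JAZ5 fell 6.59-fold. LOX3 fell by 2.15 on the log2 scale at its brightest probe, and its 3 probes ranged from -2.15 to -0.42. The lists had medians of -0.51 (adjusted p = 0.00797) and -0.84 (0.0354), and with an estimated correlation the adjusted p = 0.605 and 0.681. Without WT replicate 1, the JA metabolism median was -0.20 (adjusted p = 0.0742) and the JA response median -0.090 (0.324), while without WT replicate 3 the JA metabolism median was -0.81 (0.000357). The JA response call was also lost without d14 kai2 replicate 1 (0.0664) or 2 (0.0595). Within slides 1, 2 and 3 the JA response median was -1.92, -0.42 and 0.26, and the JA metabolism median -0.90, -0.15 and -0.04.

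Auxin response genes rose. Of 25 measured, 17 rose and none fell (19 adjusted over the list alone), with a median log2 change of 0.97 (camera adjusted p = 1.12e-07, and adjusted p = 0.427 with an estimated correlation). The early auxin genes IAA5, IAA6 and IAA14 rose 7.66-fold, 4.28-fold and 2.63-fold, and the homeobox gene HB-2, also a shade marker, rose 2.31-fold from -1.36 ± 0.07 to -0.15 ± 0.17 (adjusted p = 0.00106). The median within the 3 slides was 1.15, 1.08 and 0.47. HB-2 lies in the chromosome stretches described at the end. Of 19 auxin metabolism genes, 5 rose and none fell over all genes tested (5 and 1 adjusted over the list alone). They included YUC8 and YUC9, genes of the last step of auxin synthesis, which rose 8.09-fold and 12.1-fold, YUC9 with 2 WT arrays above background, and the auxin-conjugating enzyme gene GH3.3, which rose 2.06-fold. As a list it was not called (median 0.13, adjusted p = 0.247), and its median was -0.039 without WT replicate 2, 0.30 without WT replicate 1 and 0.28 with normexp.

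**Figure D2:**
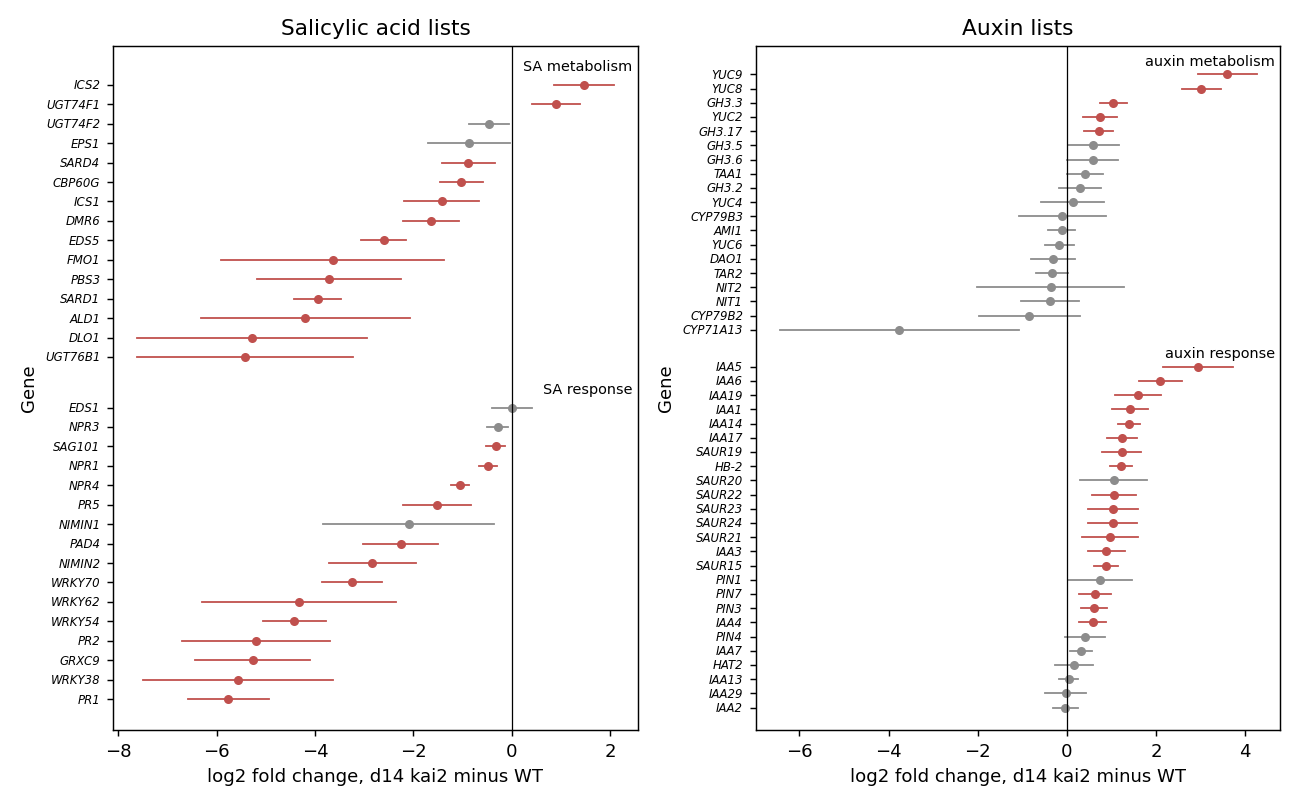
Log2 fold change, d14 kai2 minus WT (horizontal axis), of each measured gene of the salicylic acid lists (left) and auxin lists (right), with 95% intervals as lines; red marks an adjusted p under 0.05 over all genes tested. Of 16 SA response genes, 13 fell, and of 25 auxin response genes, 17 rose.

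Abscisic acid (ABA) response genes rose on balance. Of 22 measured, 11 rose and 2 fell (13 and 4 adjusted over the list alone), with a median log2 change of 0.74 (adjusted p = 0.00287, and adjusted p = 0.307 with an estimated correlation). The dehydration-responsive gene RD22 rose from 1.81 ± 0.15 to 3.26 ± 0.10 (2.73-fold, adjusted p = 0.000571), COR15A, which encodes a chloroplast protein of freezing tolerance, 4.26-fold, the dehydrin gene ERD10 1.81-fold, and HAB1, a phosphatase that restrains ABA signalling, 2.00-fold. Within the 3 slides the median was 0.60, 0.76 and 0.83. ABA metabolism genes went both ways, with 4 of 12 up and 2 down, the same when adjusted over the list alone (median 0.20, adjusted p = 0.4). That median was 0.12 without WT replicate 2 and 0.0055 with every probe on its own. Of the ABA 8'-hydroxylase genes, CYP707A2 rose 14.9-fold and CYP707A3 fell 6.35-fold. ABA1, the zeaxanthin epoxidase gene early in ABA synthesis, rose 1.62-fold, and UGT71C5, which glucosylates ABA, fell 1.64-fold.

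The other hormone lists were not called. In the brassinosteroid list 6 of 18 genes rose and 2 fell (8 and 3 adjusted over the list alone, median 0.15, adjusted p = 0.0935). The growth-promoting transcription factor genes BEE1 and BEE3 rose 3.27-fold and 2.18-fold, and BES1 rose 1.70-fold. Without d14 kai2 replicate 3 this list was called (median 0.26, adjusted p = 0.0227), and with the mean of all probes of a gene its median was 0.10. In ethylene metabolism 5 of 10 genes rose and none fell (5 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.134), with the ACC synthase genes ACS4 and ACS8 13.4-fold and 9.48-fold higher. Its median was 0.37 without d14 kai2 replicate 3, 0.060 after quantile normalization and 0.0036 with every probe on its own. Ethylene response had 4 of 15 up and 2 down (the same adjusted over the list alone, adjusted p = 0.958), a median of -0.02 and a mean of -0.04 beside an upward test direction, and its median was 0.040 without WT replicate 1. Its receptor gene ETR2 rose 1.81-fold and ERF6, in the chromosome stretches described at the end, fell 5.83-fold. In gibberellin metabolism 3 of 12 rose and 4 fell (3 and 6 adjusted over the list alone, median -0.13, adjusted p = 0.239). The biosynthesis genes GA3OX1 and GA2 fell 6.09-fold and 2.02-fold, GA20OX3 fell at least 3.47-fold and GA20OX2 rose 1.72-fold. With every probe on its own this list was called (median -0.73, adjusted p = 0.0109), as it was without both arrays of replicate 1 (median -0.17, adjusted p = 0.047). With probes above background on all 6 arrays its median was -0.028. Gibberellin response had 1 gene up, GASA6 at 2.18-fold, and 1 down, the DELLA repressor gene RGL1 at 2.97-fold, of 14 measured, the same adjusted over the list alone (median 0.16, adjusted p = 0.691, and median 0.076 without d14 kai2 replicate 3 and 0.082 without WT replicate 3). In cytokinin metabolism 3 of 21 rose and 3 fell, the same adjusted over the list alone. The median was 0.01, the mean -0.19 and the adjusted p = 0.958, and without WT replicate 1 the median was -0.15. The cytokinin oxidase gene CKX1 fell 4.07-fold and IPT1, a synthesis gene well above background on 2 mutant arrays, 9.07-fold. In cytokinin response 3 of 14 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.302), with the response regulator gene ARR9 1.70-fold higher and ARR16 2.76-fold lower. Without WT replicate 3 the median was 0.13, and with every probe on its own 0.15.

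**Figure D3:**
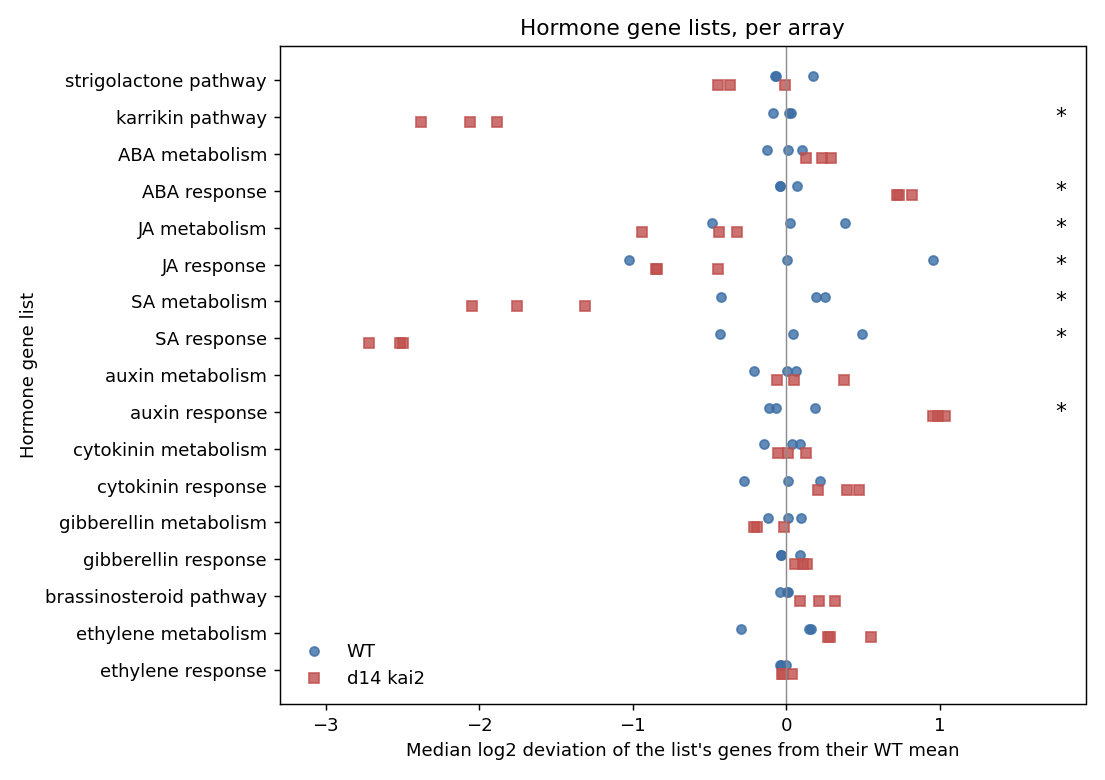
Median log2 deviation of each hormone list's genes from their WT mean (horizontal axis), per array, with WT as circles and d14 kai2 as squares; asterisks mark lists with a camera adjusted p under 0.05. The mutant arrays lay between -2.72 and -2.50 for SA response and between 0.96 and 1.04 for auxin response, while the JA response values of both genotypes overlapped.

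Among leaf processes, photosynthesis and chlorophyll genes were higher in the mutant: 14 of 20 rose and none fell (17 rose adjusted over the list alone, median 0.42, adjusted p = 6.55e-07, and adjusted p = 0.427 with an estimated correlation). The antenna gene LHCB6 rose from 7.29 ± 0.08 to 8.02 ± 0.09 (1.66-fold), and the change of GUN5, a magnesium chelatase subunit gene, was 0.68 on the log2 scale. Within slides 1, 2 and 3 the median was 0.58, 0.34 and 0.32. After quantile normalization it was 0.12 and the adjusted p = 0.057. Leaf senescence genes were lower, with 6 of 14 down and 1 up (8 and 1 adjusted over the list alone, median -0.57, adjusted p = 0.0164, and adjusted p = 0.447 with an estimated correlation). WRKY6 fell 2.12-fold, SAG21 2.40-fold, and SAG13, with 2 mutant arrays above background, fell by 4.13 on the log2 scale. With probes above background on all 6 arrays the median was -0.27 (adjusted p = 0.0329), and with normexp -0.38. That call was lost without WT replicate 3 (median -0.50, adjusted p = 0.0917), and the median within the 3 slides was -0.49, -0.28 and -0.61. Aliphatic glucosinolate genes had 1 of 12 down, MAM3 at 4.49-fold, the same adjusted over the list alone (median -0.81, adjusted p = 0.0159, and adjusted p = 0.668 with an estimated correlation), and the call was lost without WT replicate 1 (median -0.37, adjusted p = 0.0804). Within slides 1, 2 and 3 its median was -2.40, -0.70 and 0.13, so the direction turned on slide 3. Indole glucosinolate and camalexin genes had 3 of 12 down (4 adjusted over the list alone, median -0.53, adjusted p = 0.0382, and adjusted p = 0.495 with an estimated correlation), and that call was lost without WT replicate 1 (adjusted p = 0.0732), d14 kai2 replicate 1 (0.0794) or d14 kai2 replicate 2 (0.071), and with the mean of all probes of a gene (0.119). Its median within the 3 slides was -0.74, -0.37 and -0.27. In the cold and touch list 3 of 11 rose and 7 fell, the same adjusted over the list alone (median -1.03, mean -0.26, adjusted p = 0.13). It was called with normexp (0.0439), without the filter on dim probes (0.0327) and with every probe on its own (0.00178). The members that rose were cold-response regulators, with CBF2 3.91-fold and CBF3 5.01-fold higher, and among those that fell were WRKY40 at 2.38-fold and the calmodulin-like gene TCH3 at 2.04-fold. The cuticle list had 8 of 23 up and 4 down (8 and 6 adjusted over the list alone, median 0.25, adjusted p = 0.389), with BDG1 3.11-fold and the wax regulator gene MYB96 2.74-fold higher. Its median was 0.098 without WT replicate 1 and 0.078 with every probe on its own. Flavonoid and anthocyanin genes had 1 of 17 up, TT5 at 1.67-fold, and 1 down (1 and 0 adjusted over the list alone, adjusted p = 0.795). None of 17 circadian clock genes passed the test, nor adjusted over the list alone (median -0.08, adjusted p = 0.461), and the median was -0.18 after quantile normalization and -0.14 without WT replicate 1. Of those, PRR9 and PRR5 had log2 changes of 0.67 and -0.31 (adjusted p = 0.0703 and 0.0766), and passed after quantile normalization (0.0349 and 0.0377). PRR9 also passed with the slide as a block (0.0126), after median scaling (0.0371) and without d14 kai2 replicate 1 (0.0344). None of 6 heat shock genes passed, nor adjusted over the list alone (adjusted p = 0.577), with ROF2 at 0.53 (adjusted p = 0.0109 with the slide as a block) and HSP70 at 0.33 (0.16 without WT replicate 1 and 0.22 without d14 kai2 replicate 3). In the cell division list 1 of 12 genes changed, the cell cycle inhibitor gene KRP2, with a log2 change of -0.81, the same adjusted over the list alone (adjusted p = 0.461 for the list).

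Markers of other organs and cell types were read on the same arrays. Flower and floral transition genes were lower in the mutant, with 7 of 11 down and none up, the same adjusted over the list alone (median -1.32, adjusted p = 0.002, and adjusted p = 0.447 with an estimated correlation). FT, the mobile signal of flowering made in leaves, was at least 3.78-fold lower (adjusted p = 0.0892 with normexp), the floral organ genes PI and SEP1 (AT5G15800) were 2.59-fold and 3.16-fold lower, and within the 3 slides the list median was -1.31, -1.26 and -0.67. That median was -0.83 without d14 kai2 replicate 1 (adjusted p = 0.00146) and -0.63 with normexp. Salicylic acid and senescence lists were lower on the same arrays. Vascular markers were higher, with 9 of 15 up and 1 down, the same adjusted over the list alone (median 0.67, adjusted p = 0.00708, and adjusted p = 0.605 with an estimated correlation). The genes that rose included IRX5, IRX9 and IRX12, of the secondary cell wall, with log2 changes of 1.01, 1.52 and 1.13. With every probe on its own the median was 0.30 (adjusted p = 0.0328), and within the 3 slides it was 0.71, 0.84 and 0.59. The auxin response list was higher on the same arrays. Trichome markers had 2 of 10 down (4 adjusted over the list alone, median -0.29, adjusted p = 0.00797, and adjusted p = 0.427 with an estimated correlation), and with normexp background correction the median was -0.16 and the adjusted p = 0.0964. Within the 3 slides it was -0.44, -0.19 and -0.37. Root markers had 1 of 7 down (adjusted p = 0.795), shoot meristem markers 1 of 9 up and 1 down (adjusted p = 0.574) and guard cell markers 2 of 12 up and 1 down (adjusted p = 0.214), with the same counts adjusted over each list alone. In the guard cell list, the ABA-activated kinase gene OST1 and the potassium channel gene KAT1 were 1.39-fold and 1.58-fold higher.

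The genes changed at least 2-fold were unevenly spread over the chromosomes, as seen in windows of 1 Mb set after the values had been examined. Of 111 windows, 7 held more such genes than the rest of the genome (hypergeometric test, adjusted p under 0.05): chromosome 1 from 10 to 13 Mb and chromosome 4 from 9 to 13 Mb. At most 2 windows passed in any of 1000 permutations of genes over positions. Within them 216 of 1175 genes changed at least 2-fold (18.4%), against 1140 of 18170 elsewhere (6.27%). KUF1, ECS1, DDB1B, CRK6, CRK14, MSRB8, NPR4, HB-2 and ERF6 lie inside. The window of KAI2 (chromosome 4, 17 to 18 Mb) had 12.2% (adjusted p = 0.0505) and that of D14 (chromosome 3, 1 to 2 Mb) 3.91%. The window after that of KAI2 (18 to 19 Mb) had 13.1% (adjusted p = 0.0732), and 18 of its 19 changed genes were lower. A raised share around KAI2 is thus not excluded by the threshold. With the genes of the 7 windows left out, 4132 of 18182 genes changed, 1129 of them at least 2-fold, and 14 lists were called. That fit kept the windows around KAI2.

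**Figure D4:**
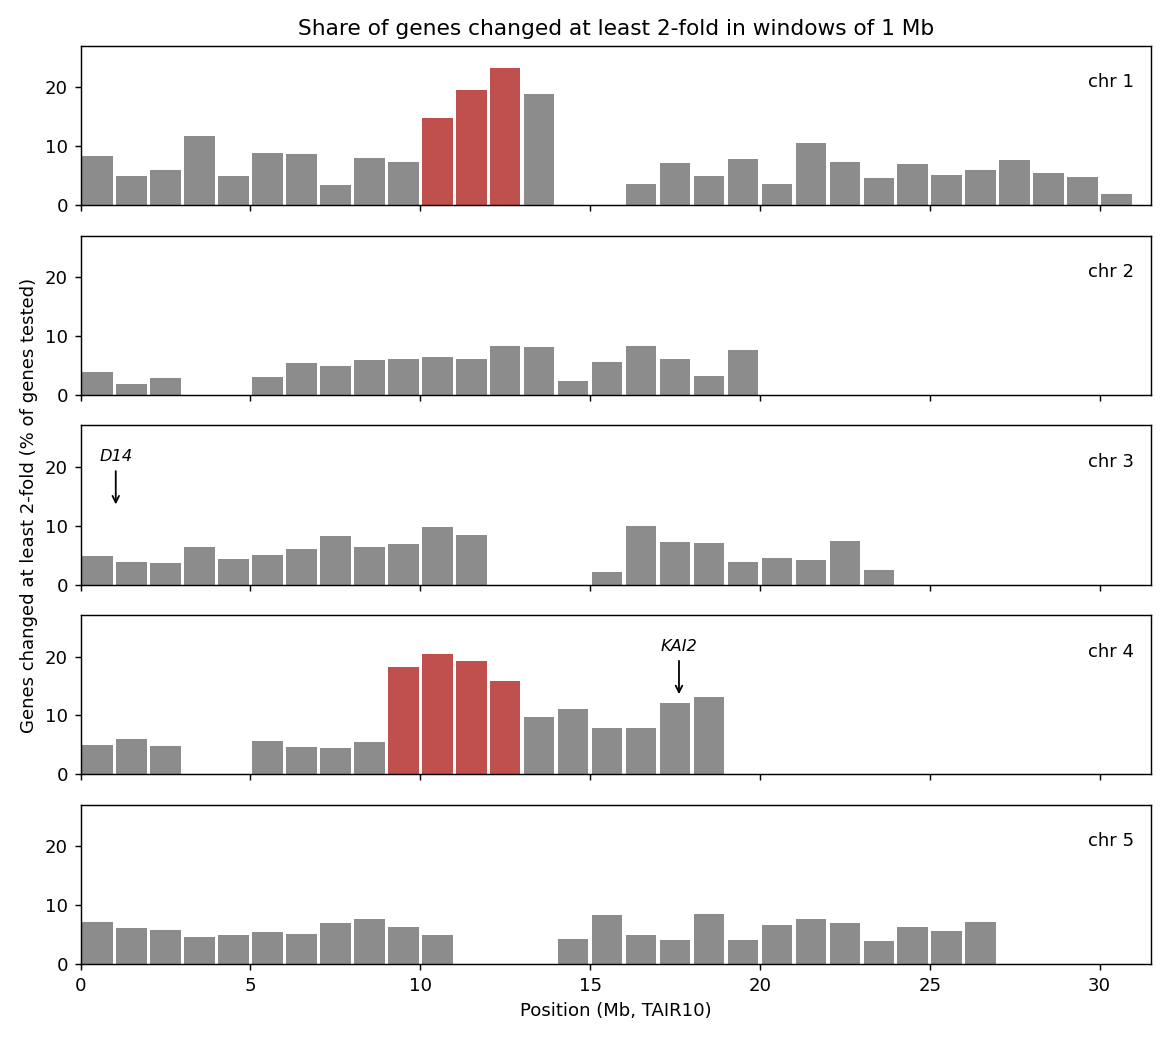
Share of tested genes changed at least 2-fold (vertical axis, %) in windows of 1 Mb along the 5 chromosomes (horizontal axis, Mb, TAIR10); windows under 20 genes are left blank, red marks an adjusted p under 0.05 and arrows mark the mutated genes. The red windows lie on chromosome 1 from 10 to 13 Mb and on chromosome 4 from 9 to 13 Mb.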

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

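Probes that could not be paired with a locus stand outside the comparisons of the report. They form 2616 units under the names of the array design, of which 416 changed in limma's test, 247 higher and 169 lower in d14 kai2. A change of at least 2-fold was seen in 154 of them, 69 higher and 85 lower. That is 5.89% of these units, where 1356 of the 19357 genes with a locus changed as much. No explanation was tested for them.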

How the results depend on the processing

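No named gene changed sign, and no list changed its test direction in a comparison where it was called. Medians of lists that were not called crossed 0: over the fits leaving out arrays they spanned -0.080 to 0.33 for auxin metabolism, -0.15 to 0.098 for cytokinin metabolism and -0.075 to 0.040 for ethylene response, and those of flavonoid genes, shoot meristem and root markers also changed sign in some setting. Of 132 named genes besides D14 and KAI2, 75 kept direction and side of the threshold in every setting, and 54 lost their call in at least 1. The series table equals the processed signals and moved nothing. The replicate block (slide) gave 6024 changed genes and 1363 of at least 2-fold, changed no list call, and among genes named in the report changed those of PRR9 and ROF2 alone. With the slide as a random block 7665 genes changed. Genes changed at least 2-fold numbered 853 with normexp, 839 of them shared with the 1356. Leaving out arrays or replicate numbers gave 1226 to 4196 changed genes and 873 to 1383 of at least 2-fold, with fewer arrays. D14 ranged from -0.46 to -0.32 over these fits and was not called after median scaling (-0.33), without the dim-probe filter (-0.37), as the mean of its probes (-0.27) or with unpaired units kept (-0.37). With an estimated correlation 0 lists and 0 families were called. For the karrikin list, camera's unadjusted p was 1.65e-08 at the preset 0.01 and 0.00498 with its estimate of 0.0134. The size of the correlation thus does not account for the loss there, and its cause was not tested. Medians do not move for the karrikin pathway (-2.11), ABA response (0.74), JA metabolism (-0.51) or JA response (-0.84). Nor do they for SA metabolism (-1.64), SA response (-2.54) or auxin response (0.97). fry, which does not compare with other genes, did not call JA metabolism (-0.51), JA response (-0.84) or aliphatic glucosinolate (-0.81) and called the strigolactone (-0.36), ABA metabolism (0.20), auxin metabolism (0.13), gibberellin metabolism (-0.13), brassinosteroid (0.15) and ethylene metabolism (0.21) lists. The strigolactone list was called with probes above background on all 6 arrays (-0.37), a filter that leaves out MAX3 and MAX4, which rose. It was also called with every probe on its own (-0.36), as was gibberellin metabolism (-0.73). Over the fits leaving out arrays, the medians spanned -0.48 to -0.16 for the strigolactone list, -0.91 to -0.18 for JA metabolism, -1.29 to -0.0900 for JA response, -0.200 to -0.0936 for gibberellin metabolism and 0.13 to 0.27 for the brassinosteroid list. Where not stated, the cause was not tested. Signal over background limits the folds of the 39 and 155 changed genes that were dim in WT or in the mutant.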

Other observations

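The tests of the chromosome windows, of families without the window genes, of linked variants and of the estimated correlation of the JA lists were chosen after the results were seen. Families of genes that share the letters of their symbol were searched without regard to hormones. Of 195 families, 19 were called by camera, and none with an estimated correlation (adjusted p = 0.804 for each). Among receptor-like proteins (RLP), many of which act in immunity, 27 of 45 fell and 3 rose (median log2 change -0.82, adjusted p = 1.19e-06). In the WRKY transcription factors 19 of 51 fell and 4 rose (median -0.45). In the cysteine-rich receptor-like kinases (CRK) 17 of 33 fell and 6 rose (median -0.89, adjusted p = 0.000685), but 20 of the 33 lie in the windows on chromosomes 1 and 4 described in the report, 13 of them down and 4 up. With the window genes left out, the other 13 CRK genes had 4 down and 2 up and were not called (median -0.19, adjusted p = 0.517), while RLP (3.75e-07) and WRKY (6.3e-06) were. In that fit 18 families were called. Cyclic nucleotide-gated channels (CNGC, 6 of 15 down) and glutamate receptor-like channels (GLR, 7 of 11 down) were also lower. Other families were higher. Of 16 small auxin up RNA genes (SAUR), 13 rose (median 1.03, adjusted p = 1.49e-05), and of 13 expansins (EXPA), 9 rose and 1 fell (median 0.66). Large-subunit ribosomal protein genes (RPL) had 10 of 21 up (median 0.39), and light-harvesting genes (LHCB) 8 of 9 up (median 0.49). These directions held under quantile, median and normexp scaling, but with normexp the medians were smaller for RLP (-0.33), WRKY (-0.28) and CRK (-0.27), and the LHCB call was lost under quantile normalization (median 0.14, adjusted p = 0.243, against 0.00139 to 0.00458 under the others).

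In the windows on chromosomes 1 and 4, 18.4% of genes changed at least 2-fold, against 6.27% elsewhere. Among genes with several probes above background on all arrays, at least 1 of them called 2-fold, the probes disagreed by more than 1 on the log2 scale in 16 of 48 inside the windows (33.3%) and in 32 of 242 outside (13.2%). The odds ratio was 3.26 (95% interval 1.5 to 6.97), with Fisher's exact p = 0.00219. Probes that move the same way by unequal amounts also count as disagreeing, as at AT4G20860 (-4.54 to -1.17). The size of change was not matched between inside and outside. Some disagreeing genes outside lie farther along chromosome 4, as AT4G33910 (-4.16 to -0.065) and AT4G39900 (-3.65 to 0.14) do, and others on other chromosomes. The group outside is thus not free of the neighbourhood of KAI2, and whether a segment extends beyond the windows was not tested. The test therefore does not decide on regulation of neighbouring genes as the whole cause. A candidate explanation is that the mutant carries segments of another accession there, whose sequence may differ under the probes, while real expression differences between alleles and the origin of such segments stay open. In RPP5, a resistance gene of chromosome 4 singled out after its values were seen, the change ranged from -5.73 to 0.96 over 4 probes, 1 other locus being matched by its brightest probe.

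Genes of the 7 rich windows are not the whole cause of the fall of the SA lists, since NPR4 and GRXC9 are the only members there. The fit without window genes therefore removed little and could hardly move the medians. It kept the windows around KAI2 (chromosome 4, 17 to 19 Mb), so it does not bear on SA genes there. In that fit the SA response median was -2.54 (adjusted p = 7.73e-08) and the SA metabolism median -1.64 (4.23e-05). Over the fits with the preset correlation the camera adjusted p ranged from 2.9e-12 to 2.39e-06 and from 1.89e-07 to 0.00228. A variant in such a segment could still act on SA genes elsewhere in the genome. The series has 0 groups other than WT and d14 kai2, so variants linked to the mutations and acting in trans cannot be told apart from loss of D14 and KAI2. ACD6 promotes SA accumulation and was singled out after its values were seen. It lies at 8.3 Mb of chromosome 4, outside the windows, and fell 6.77-fold at its brighter probe and by 4.93 on the log2 scale at the other. These probes disagree by 2.17 on the log2 scale, so its place outside the windows does not clear them of sequence differences. A later flowering stage of WT, where floral markers were higher, was not tested as a cause and stays open, as does the loss of either receptor alone.

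In the JA lists, WT arrays alone spanned -1.03 to 0.95 in the JA response median, more than the 3 mutant arrays (-0.85 to -0.45). Without WT replicate 1 the fall was -0.0900 (adjusted p = 0.324), in a range of adjusted p from 0.000456 to 0.434 over the fits that leave out arrays. WT replicate 1 (0.95) thus carried much of the fall, but WT replicate 3 (-1.03) lay below every mutant array. The pattern is a spread over the WT arrays rather than 1 high array alone. With an estimated correlation the JA response list had an adjusted p of 0.681, but no list was called that way, so variation between WT arrays beyond the preset correlation cannot be told apart from a genotype effect by that test. The estimate itself was 0.543 for JA metabolism and 0.548 for JA response, above the preset 0.01, so their calls at the preset value are less certain. The same holds for other called lists, among them SA response (0.21), SA metabolism (0.274) and auxin response (0.27). It also holds for flower (0.244), photosynthesis (0.199) and vascular (0.592) genes. With fry the adjusted p of JA metabolism and JA response was 0.14 and 0.223. A biological difference between genotypes stays open.

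The real split of the 6 arrays called 4744 genes with limma, and the highest of the other splits 0, including the 3 that part the arrays of every slide as the real one does. It was 1 of 10 splits with as many genes, and 10 splits are too few for a share under 0.05.

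CBF2 and CBF3, which rose, lie at the edge of the rich windows (chromosome 4, probes from 13015631 and 13018359). MAX3 and MAX4 rose while MAX1, downstream of both, fell.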
